A study of Chlamydomonas reinhardtii with 9 samples.

How the data were processed

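Chlamydomonas reinhardtii CC-4532 was sampled 9 times after a wash in TAP medium without Fe-EDTA. The deposited table holds 17301 transcripts with names, descriptions and 18 columns of values, 2 per time point, with 0 columns of values per sample left unused. The series design text calls the 2 columns of a time biological duplicates, while 1 sample is registered per time. The values are RPKM (reads per kilobase of transcript, scaled to library size), as deposited by the authors; the header names no unit, and the unit was read from the values. Reads had been aligned with Bowtie per the submitters' processing notes. Its version, the genome build, the counting tool and any filter are not given in the sources used here. Gene names and descriptions were taken from the deposited table, and the separate table of RefSeq names was not used. Where copies of a gene are near-identical, how the authors' counting divided their reads is not known.

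The reads behind each value were recovered with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, since each value is a whole number of reads divided by transcript length and library size. A length was solved for 16688 transcripts (96.5%), with a median of 2268 bases, and 99.97 to 100% of their values per column were whole within 0.05 reads. As a length was accepted only where it made the values whole, that share follows largely from the selection. The libraries held 13.2 M to 33.4 M reads. A value of 0 allows up to 3 reads in a library at 95% confidence, which is 0.0395 to 0.100 RPKM at the median length. Tests used the RPKM values and not the recovered reads.

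The design written before the data were examined allowed for counts. As the values are normalized, its alternative for such values was used: limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1) of the mean of both columns per time, with log2(hours + 0.5) as a covariate, 9 values and 7 residual degrees of freedom. A natural spline with 3 degrees of freedom left 5. The change along time is the fitted difference between 0 and 48 h. Genes with at least 1 RPKM in at least 3 time points entered, 13077 in all, and p-values were adjusted by Benjamini-Hochberg at 0.05. Genes at least 4-fold from 0 h were counted without a test among 12712 genes with a mean of at least 1 RPKM. After the table was seen to hold 2 columns per time, limma-trend was also run on all 18 columns with time as a factor and duplicate number as a block, which leaves 8 residual degrees of freedom, and genes were called at an adjusted p below 0.05 and at least 2-fold.

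That duplicate 1 of one time belongs with duplicate 1 of another comes from the numbers in the column names. It was checked by correlating the difference between duplicates across genes between times: over 36 pairs of times the correlation was 0.31 to 0.73, with a median of 0.50. Over all times, duplicate 2 differed from duplicate 1 by at least 2-fold in 33 genes that were higher and 12 that were lower.

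Gene lists were fixed before the data, 29 in number, by symbol. They were iron uptake, ferritin and iron-sulfur assembly, photosystem I, photosystem II, photoprotection, electron carriers, tetrapyrroles, plastid membrane lipids, desaturases, betaine lipid and phospholipids, triacylglycerol synthesis, fatty acid synthesis, lipid breakdown, respiration, redox enzymes, other metals, acetate use, Calvin cycle and starch, inorganic carbon concentration, nutrient supply, fermentation, chaperones, cell cycle, flagella, cytosolic ribosome, plastid ribosome, proteasome, autophagy and histones. The 25 with at least 5 tested members were tested with camera at a preset correlation of 0.01, along time and, after the table was seen, at each time (200 tests). Members past the threshold were also counted with p adjusted over the list alone. The median of a list at 48 h was placed among 10000 random lists of equal size drawn from 20 bins of mean level. Groups of described desaturases, lipases and acyltransferases and the LHCBM family were added later, because few lipid genes carry a listed symbol.

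Named genes followed a rule fixed beforehand: members of the iron and lipid lists, the 8 largest rising and falling trends, the 5 highest and 5 lowest changes at 0.5 and 48 h, the 4 members with the steepest slope of each other list, the 5 smallest spline p-values without a trend, and at most 2 genes without a symbol in each direction. Members of the groups added later were named after their values were seen.

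Alternatives were median centring, pseudocounts of 0.1, 0.5 and 5, no filter, a filter of 5 RPKM, rank of time or hours as the scale, a spline with 2 degrees of freedom, a threshold of 0.01, other baselines, an estimated correlation, no block, each duplicate alone, and leaving out each time or column. Methods were tested on simulated data, with the spread of each gene taken from the difference between its duplicates. Each test met the shape of change it fits. This was a line for the trend, a mid-course peak for the spline and a step at 48 h for the others. Recovery and false calls therefore do not carry over to genes that follow another course. Of 100 genes changed by 1.5 and 100 by 3 on the log2 scale, the trend recovered 90 and 94 with 16 false calls among 12776 genes, the spline 69 and 98 with 11 among 12779, the duplicate test at 48 h 79 and 95 with 1 among 12772, and the 4-fold count 2 and 92 with 7 among 12577. Camera called a simulated rising list of 20 genes and not an unchanged one, and their medians lay at percentiles 100 and 55.6 of random lists. The simulated genes varied independently, so this does not test the preset correlation on lists whose members move together. In the data the estimated correlation of the photosystem I list around the straight-line fit was 0.983, which includes any departure from the line that its members share. Read recovery solved 100% of 4000 simulated transcripts, with 99.8% of values right. Figures were drawn with matplotlib 3.10.9.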

Results

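Cells of the green alga Chlamydomonas reinhardtii, strain CC-4532, were grown in light on acetate medium, washed without iron and placed in the same medium made without Fe-EDTA. RNA was sequenced at 9 times, from 0 h through 0.5, 1, 2 and 4 h, then 8 and 12 h, to 24 and 48 h, giving 18 columns of RPKM, 2 per time, for 17301 transcripts. The libraries held 13.2 M to 33.4 M counted reads, as recovered from the values themselves. Duplicates of a time point correlated at 0.981 to 0.989 across genes, which are not independent of each other, and 88.1 to 96.2% of genes lay within 1.5-fold between them. Changes were tested in 13077 genes with limma-trend on log2(RPKM + 1), each time against 0 h with 2 columns per time, and a gene was called at an adjusted p below 0.05 and a change of at least 2-fold. This scale understates the change of weakly expressed genes. A culture supplied with iron was not among the samples at any time, so each change is a difference from the washed cells at 0 h, and age of the culture, transfer to fresh medium and loss of iron act together. The p-values measure only the spread between these columns.

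Iron is needed in quantity by photosystem I, the cytochrome b6f complex and the respiratory chain, and an alga that loses its supply has to import more, spend less and protect itself from misdirected electrons. The transcripts moved in waves. Genes of iron uptake rose at the first sampling, when several genes for concentrating inorganic carbon and most of those tested for fermentation were already lower. Most transcripts of the photosystem II antenna climbed until 12 h and those of photosystem I until 4 to 8 h, and both collapsed by 48 h, and many genes of flagella were lower from the first sampling. Among lipid genes, some desaturases and lipases rose, while other desaturases and some genes of betaine lipid and fatty acid synthesis were lower at 48 h.

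Of the 13077 genes, 737 were higher and 455 lower than at 0 h after 0.5 h, 1322 and 2357 after 12 h, 1930 and 835 after 24 h, and 2410 and 2068 after 48 h. The median change of 12712 genes with a mean of at least 1 RPKM was, on the log2 scale, 0.14 at 0.5 h, 0.18 at 1 h, 0.06 at 2 h, -0.06 at 4 h, -0.17 at 8 h, -0.14 at 12 h, 0.28 at 24 h and 0.14 at 48 h. With each column centred on its median the counts were 459 higher and 656 lower at 0.5 h, 1770 and 1872 at 12 h, 913 and 1427 at 24 h, and 1870 and 2512 at 48 h, so which direction led at 0.5, 24 and 48 h rested on the scaling. Between neighbouring times the first 0.5 h moved 737 genes up and 455 down, the next 0.5 h moved 17 and 51, and the step from 12 to 24 h moved 1903 and 293. The last step, from 24 to 48 h, moved 971 up and 2101 down. These step counts were not centred. The median change of all genes went from -0.14 at 12 h to 0.28 at 24 h, so which direction led in a step may rest on the scaling. Without a test, 21 genes were at least 4-fold higher and 43 at least 4-fold lower at 0.5 h among 12712 genes, 250 and 609 at 12 h, 202 and 180 at 24 h, and 531 and 645 at 48 h. After centring, the 4-fold counts were 338 and 469 at 12 h and 123 and 300 at 24 h.

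**Figure D1:**
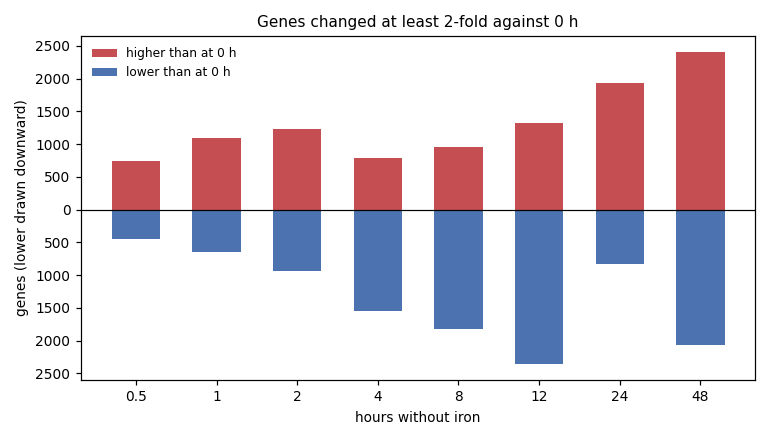
Genes at least 2-fold higher or lower than at 0 h with an adjusted p below 0.05 (limma-trend, 2 columns per time) at each time without iron.

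A straight line over log time gave fewer genes than a curve, and how many genes changed course was not counted. With the mean of both columns per time, limma-trend gave 657 genes rising and 481 falling along time (798 and 829 after centring), where 3566 passed an unadjusted p below 0.05, and a spline with 3 degrees of freedom gave 6415, of which 5284 had no linear trend and 7 genes had a trend alone. The linear counts depended on single times. Without the 0.5, 1 or 2 h values the rising genes numbered 343, 373 and 385 and the falling genes 214, 244 and 294; without the 12, 24 or 48 h values the falling genes numbered 316, 898 and 253. The spline count was 4261 without 8 h. The choice of a log time scale, the gene lists and their members were fixed before the data were examined, while testing each time with both columns was chosen after the table was seen to hold 2 columns per time.

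Cells that run short of iron put a reductase, a ferroxidase and a permease on the cell surface, together with secreted iron-binding proteins. Genes for each of these parts rose within 0.5 h. FRE1 (Cre04.g227400), the ferric-chelate reductase that starts this route, went from 0.200 RPKM at 0 h to 27.8 at 0.5 h and 1804 at 12 h, a log2 change of 4.50 (SE 0.22, n = 2, limma-trend adjusted p = 1.6e-07) and then 10.54. The multicopper ferroxidase FOX1 (Cre09.g393150) and its partner permease FTR1 (Cre03.g192050) rose by 1.77 and 1.40 at 0.5 h and by 3.35 and 3.57 at 24 h. FEA1 (Cre12.g546550), a secreted protein that holds iron near the cell, was already abundant at 0 h, with 1029 and 240.1 RPKM in duplicates 1 and 2, and reached 7933 RPKM at 24 h (log2 change 3.99). IRT1 (Cre12.g530400), a transporter of the ZIP family, rose by 3.45 at 4 h and 4.26 at 24 h, then stood at 0.658 RPKM at 48 h against 0.835 at 0 h. FOX2 (Cre12.g531200), a second multicopper oxidase, ran the other way early, with 9.90 RPKM at 0 h, 5.06 at 1 h and 19.2 at 48 h. Of the 6 listed uptake genes tested, 5 were higher at 0.5 h and 1 was not called, and 4 were higher at 48 h with the other 2 not called; the counts were the same adjusted over the list alone. The median of the list was 1.59 at 0.5 h, 3.34 at 12 h and 3.78 at 24 h. Along time, 3 of the genes had a rising trend, 4 adjusted over the list alone.

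**Figure D2:**
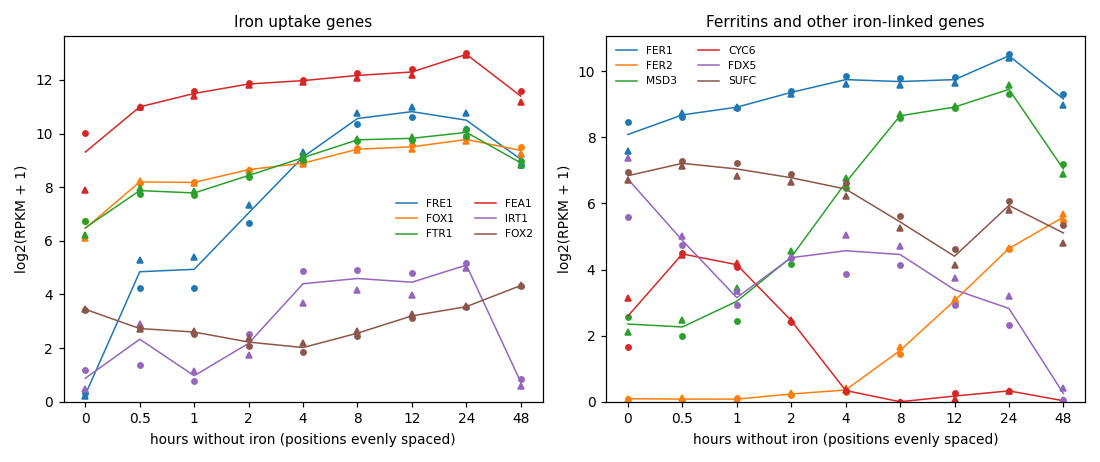
RPKM on a log2(RPKM + 1) scale of iron uptake genes (left) and of FER1, FER2, MSD3, CYC6, FDX5 and SUFC (right) at each time. Circles are duplicate 1, triangles duplicate 2 and lines their means. FRE1 reached 1804 RPKM at 12 h.

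Ferritin stores iron in the plastid, and both of its genes rose. FER1 (Cre09.g387800), the abundant form, went from 271 to 1414 RPKM by 24 h (log2 change 2.44, SE 0.17, limma-trend adjusted p = 8.2e-08). FER2 (Cre13.g574500) was nearly silent at 0 h, with 2 and 4 reads, and reached 7.32 RPKM at 12 h, 23.9 at 24 h and 47.1 at 48 h; its fitted change along time was 5.93 (SE 0.80, limma-trend adjusted p = 0.00571), a size set largely by the added 1 RPKM. Among genes that build plastid iron-sulfur clusters, the scaffold genes SUFC (Cre07.g339700) and SUFD (Cre12.g513950) changed by -2.45 and -2.34 at 12 h, and SUFB (Cre15.g643600) by -1.96. The mitochondrial scaffold gene ISU1 (Cre13.g568850) instead rose by 1.54 at 48 h. Of 13 tested ferritin and cluster assembly genes, 2 were higher and 5 lower at 12 h, 2 and 1 at 24 h, and 3 and 3 at 48 h, with the rest not called, and equally many adjusted over the list alone. With centring 2 were higher and 3 lower at 12 h, and 2 higher and 5 lower at 24 h. Camera gave this mixed list no direction along time (adjusted p = 0.361).

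Genes for handling reactive oxygen rose in part. MSD3 (Cre16.g676150), a manganese superoxide dismutase able to stand in for iron enzymes, went from 4.10 RPKM at 0 h to 699.8 at 24 h (log2 change 7.11, SE 0.25, limma-trend adjusted p = 5.6e-10). SOUL1 (Cre06.g299700), a heme-binding protein gene, rose by 3.37 at 12 h, and the catalase/peroxidase gene CAT2 (Cre01.g045700) by 2.28. PRX6 (Cre10.g422300), a thioredoxin-dependent peroxidase gene, rose early, by 2.18 at 2 h, and was lower by 48 h (-2.67). Of the 22 tested redox genes, 8 were higher and 2 lower at 12 h (11 and 0 after centring), and 7 and 6 at 48 h, with the same counts adjusted over the list alone. In the 11-gene list for other metals, 1 was higher and 3 lower at 48 h, with 7 not called and equal counts adjusted over the list alone; the copper transporter gene CTR2 (Cre10.g434350) fell by 2.96 within 0.5 h. The median trend of the list was 0.23 while camera leaned down (adjusted p = 0.926).

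Concentrating inorganic carbon costs energy and is needed when CO2 is scarce; most of its genes fell, several of them by the first sampling. NAR1.2 (Cre06.g309000), which carries bicarbonate into the plastid, went from 540.2 RPKM at 0 h to 53.3 at 0.5 h (log2 change -3.61, SE 0.60, limma-trend adjusted p = 2.5e-04) and 0.400 at 48 h (-8.61). The plastid envelope carrier gene CCP2 (Cre04.g222750), the soluble protein gene LCID (Cre04.g222800) and LCR1 (Cre02.g136800), a MYB-type regulator of the pathway, changed by -3.46, -3.40 and -3.20 at 0.5 h. LCI1 (Cre03.g162800), a plasma membrane channel gene, followed at 1 h (-3.22) and was listed at 0 RPKM at 24 and 48 h. The periplasmic carbonic anhydrase gene CAH1 (Cre04.g223100) had 62.1 RPKM at 0 h, with 34.6 and 89.6 in duplicates 1 and 2, then 571 at 0.5 h and 0.136 at 48 h (-5.64). Its call at 0.5 h (limma-trend adjusted p = 0.0218) was lost without duplicate 1 of 0 h (0.200) or duplicate 2 of 0.5 h (0.141). CAH8 (Cre09.g405750), another carbonic anhydrase gene, was the member higher at 48 h, by 2.39. Of the 16 tested genes, 2 were higher and 7 lower at 0.5 h, 2 and 13 at 12 h, and 1 and 14 at 48 h, also when adjusted over the list alone. The list's median was -0.86, -3.54 and -4.38 at 0.5, 12 and 24 h. Along time 10 fell and 1 rose, 13 and 1 adjusted over the list alone.

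Most of the tested fermentation genes, which algae use when oxygen runs low, were also lower at 0.5 h. PFL1 (Cre01.g044800), pyruvate-formate lyase, changed by -1.38 at 0.5 h and -2.72 at 2 h, and PFR1 (Cre11.g473950), the iron-sulfur enzyme pyruvate-ferredoxin oxidoreductase, by -2.39 at 0.5 h and -5.76 at 48 h. The ferredoxin gene FDX5 (Cre17.g700950), known from anoxic cells, changed by -1.61 at 0.5 h and -6.24 at 48 h. HCP2 (Cre02.g129550), a hybrid-cluster protein gene, instead rose by 3.94 at 48 h, and its trend was 3.87 (SE 0.54, limma-trend adjusted p = 0.00631). Of 7 tested genes, 5 were lower at 0.5 h and the other 2 not called, and 1 was higher and 2 lower at 48 h, the same counts adjusted over the list alone. The list's median trend was -0.11 but its mean 0.16 and the direction of the camera test up (adjusted p = 0.772).

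Some genes that bring acetate into metabolism rose. ACS3 (Cre07.g353450), acetyl-CoA synthetase, rose from 67.4 to 333 RPKM within 0.5 h (log2 change 2.28, SE 0.10, limma-trend adjusted p = 1.6e-07) and by 3.64 at 12 h. The glyoxylate cycle genes ICL1 (Cre06.g282800), isocitrate lyase, and MAS1 (Cre01.g057800), malate synthase, rose by 1.97 and 2.23 at 12 h. ACK1 (Cre09.g396700), acetate kinase, went the other way early, with 5.01 RPKM at 0 h and 1.77 at 0.5 h (-1.09), a change under 2-fold without duplicate 1 of 0 h (-0.76), without duplicate 2 of 0.5 h (-0.96) or with a pseudocount of 5 (-0.55). Among 21 tested genes of acetate use and the TCA cycle, 3 were higher and 2 lower at 4 h (3 and 0 after centring), 10 were higher at 12 h and 11 not called, and 6 were higher and 1 lower at 48 h (4 and 3 after centring), equally adjusted over the list alone. Of 47 respiratory genes, 1 was lower at 0.5 h, 3 at 4 h, 1 higher and 1 lower at 12 h (3 and 1 after centring; 31 were higher at an unadjusted p below 0.05), 2 were lower at 24 h, and 14 at 48 h with 33 not called (17 lower after centring), as when adjusted over the list alone. The complex III gene QCR6 (Cre16.g660851) and the complex I gene NUOA8 (Cre07.g333900) changed by -1.80 and -1.36 at 48 h, while SDH4 (Cre01.g020300), of succinate dehydrogenase, had risen by 1.23 at 12 h.

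**Figure D3:**
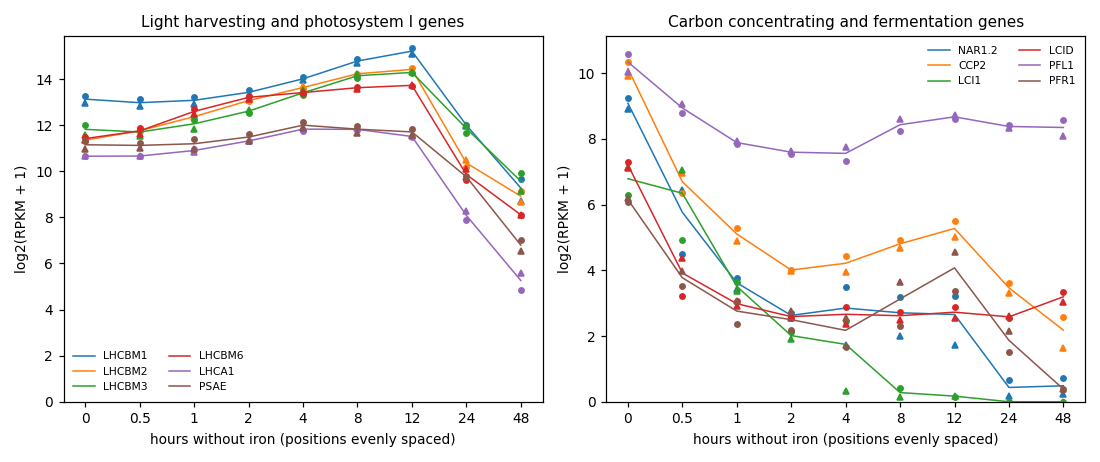
RPKM on a log2(RPKM + 1) scale of antenna and photosystem I genes (left) and of inorganic carbon and fermentation genes (right) at each time; circles are duplicate 1, triangles duplicate 2 and lines their means. NAR1.2 went from 540.2 RPKM at 0 h to 53.3 at 0.5 h.

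Photosystem I carries more iron than any other complex of the thylakoid, and its dismantling is a known early step of iron deficiency. Here most of its tested transcripts were higher at 4 h, before they fell. LHCA1 (Cre06.g283050), an antenna protein of photosystem I, rose from 1611 to 3638 RPKM by 4 h (log2 change 1.17), then dropped to 271 at 24 h and 37.4 at 48 h (-5.44, SE 0.15, limma-trend adjusted p = 1.0e-11). LHCA2 (Cre12.g508750) and LHCA4 (Cre10.g452050) followed the same course, with 1.40 and 1.86 at 4 h and -4.04 and -5.07 at 48 h. The core subunit genes PSAE (Cre10.g420350) and PSAL (Cre12.g486300) changed by -4.36 and -3.82 at 48 h. Of 19 tested genes, 13 were higher at 4 h and 4 at 12 h (7 after centring), 18 were lower at 24 h and 19 at 48 h, equally many adjusted over the list alone. The list median went from 1.03 at 8 h to -1.77 at 24 h and -4.04 at 48 h. Because the genes rose and then fell, limma-trend gave none of them a linear trend at the threshold, and 13 had an unadjusted p below 0.05; the spline gave 19.

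Most transcripts of the LHCBM family, in the antenna of photosystem II, also rose and then fell. LHCBM1 (Cre23.g766250) rose from 8972 to 37990.0 RPKM at 12 h (log2 change 2.08, SE 0.16, limma-trend adjusted p = 8.4e-08) and stood at 618 at 48 h (-3.93). LHCBM2 (Cre12.g548400) and LHCBM4 (Cre06.g283950) rose by 3.07 and 3.11 at 12 h, and LHCBM4 and LHCBM8 (Cre06.g284250) changed by -2.78 and -4.36 at 24 h. The LHCBM genes are near-identical copies whose reads the counting may have shared, so values of single members are uncertain and their sum is safer. Summed, they made up 2.51 and 2.03% of all RPKM at 0 h in duplicates 1 and 2, 12.2 and 11.1% at 12 h, 1.30 and 1.47% at 24 h, and 0.328 and 0.209% at 48 h. This family, grouped after the values were seen, had 8 of 8 genes higher at 12 h and 7 lower at 48 h. Of 18 tested genes of photosystem II and its antenna, 9 were higher and 1 lower at 12 h (12 and 0 after centring), 6 lower at 24 h and 12 lower at 48 h, with the rest not called and the same counts adjusted over the list alone.

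Genes for other parts of the photosynthetic apparatus fell late. FNR1 (Cre11.g476750), which passes electrons from ferredoxin to NADP, and PETO (Cre12.g558900), bound to the cytochrome b6f complex, changed by -3.36 and -2.35 at 48 h. CYC6 (Cre16.g651050), the heme protein that replaces plastocyanin, rose by 2.06 at 0.5 h and was listed at 0 RPKM at 8 h. Of 15 electron carrier genes, 1 was higher and 8 lower at 24 h and 11 lower at 48 h, equally adjusted over the list alone. Most tested genes of chlorophyll and heme synthesis were higher at 1 h, and most were lower at 48 h. PBGD1 (Cre16.g663900), porphobilinogen deaminase, and GSA (Cre03.g158000), which makes the precursor aminolevulinate, rose by 2.50 and 1.47 at 0.5 h. CRD1 (Cre07.g346050), a diiron enzyme of chlorophyll synthesis, fell by 4.44 at 48 h (SE 0.13, limma-trend adjusted p = 1.8e-11). Of 19 tetrapyrrole genes, 13 were higher at 1 h, 11 at 4 h, and 11 lower at 48 h, the same adjusted over the list alone, and the median went from 1.54 at 2 h to -1.21 at 48 h. At 24 h this median was 0.05, and -0.28 after centring.

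Several genes against excess light fell. LHCSR2/LHCSR3.1 (Cre08.g367500), a stress-related antenna protein with near-identical copies, changed by -5.21 at 12 h and -6.08 at 24 h (SE 0.38, limma-trend adjusted p = 3.7e-08), and the early light-inducible genes ELI3 (Cre02.g130500) and ELI4 (Cre02.g143550) by -2.44 and -1.94 at 12 h. Of 5 tested genes of this list, 2 were higher and 2 lower at 1 h (1 and 2 after centring), 1 was higher and 3 lower at 12 h, and 4 were lower at 48 h and 1 was not called, as when adjusted over the list alone. In the Calvin cycle and starch list of 33, 9 were higher at 8 h, and 6 higher and 12 lower at 48 h, equally adjusted over the list alone. PRK1 (Cre12.g554800), phosphoribulokinase, rose by 1.36 at 8 h and was lower by 48 h (-2.42), and RBCS1 (Cre02.g120100), the small subunit of Rubisco, fell by 2.22. The symbol SBP1 in that list belongs in the table to a sulfate binding protein (Cre06.g257000).

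Membrane lipids are named in the title of the series. Among the lipid genes that changed were those for fatty acid desaturation and for the betaine lipid that replaces phosphatidylcholine in this alga. FAB2 (Cre17.g701700), the plastid stearoyl desaturase that makes oleate, rose by 1.48 at 12 h and 1.41 at 48 h. DES6 (Cre13.g590500), the plastid omega-6 desaturase, went from 944 RPKM at 0 h to 3671 at 12 h (1.96), 552 at 24 h and 5957 at 48 h (2.66, SE 0.10, limma-trend adjusted p = 9.9e-11). FAD5D (Cre03.g209600), a further desaturase gene, rose by 2.51 at 12 h. In contrast FAD7 (Cre01.g038600), the plastid omega-3 desaturase, fell by 3.31 at 48 h, as did Cre01.g037700, described as a desaturase (-2.93). Cre17.g711150, described as a delta-12 desaturase, rose by 1.33 at 0.5 h and was lower at 48 h (-2.32). Of 4 listed desaturases, 3 were higher at 12 h, and 2 were higher and 1 lower at 48 h, equally adjusted over the list alone. Grouped by the descriptions in the table after the values were seen, 6 desaturases gave 1 higher and 3 lower at 48 h.

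**Figure D4:**
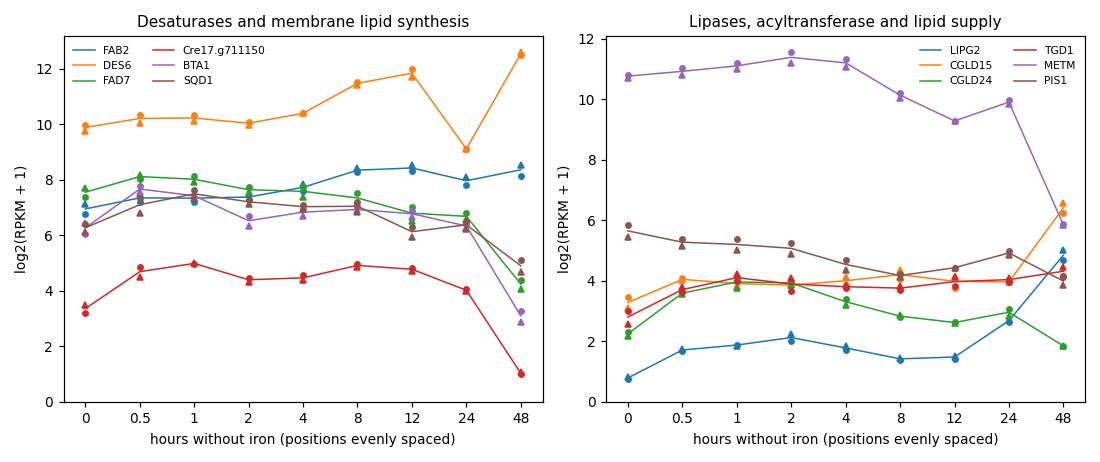
RPKM on a log2(RPKM + 1) scale of desaturase, betaine lipid and sulfolipid genes (left) and of lipase, acyltransferase, lipid transfer and phospholipid genes (right) at each time; circles are duplicate 1, triangles duplicate 2 and lines their means. BTA1 stood at 202 RPKM at 0.5 h and 7.54 at 48 h.

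BTA1 (Cre07.g324200), the enzyme of betaine lipid synthesis, rose from 76.0 to 202 RPKM by 0.5 h (log2 change 1.41) and fell to 7.54 by 48 h (-3.17, SE 0.15, limma-trend adjusted p = 1.1e-09). METM (Cre06.g250200), which makes the S-adenosylmethionine that its headgroup needs, changed by -4.91 at 48 h, and PIS1 (Cre10.g419800), phosphatidylinositol synthase, by -1.65. Of the 8 tested genes of betaine lipid and phospholipid synthesis, 2 were lower at 12 h, where centring added 1 higher gene, and 3 at 48 h, with 5 not called and equal counts adjusted over the list alone; the symbol CDS1 belongs in the table to a mitochondrial ABC transporter. For plastid membrane lipids, SQD1 (Cre16.g656400), which makes the sulfolipid headgroup, rose by 1.22 at 1 h and was lower at 48 h (-1.38), and TGD1 (Cre06.g268200), part of a lipid importer of the plastid envelope, rose by 1.52 at 48 h. Of 8 tested genes of that list, 3 were higher at 1 h, and 1 was higher and 1 lower at 48 h, with 6 not called, as when adjusted over the list alone. Its median at 48 h was 0.10, and -0.07 after centring. PGD1 is described there as a phosphoglycerate dehydrogenase and PGP1, PGP2 and PGP3 as phosphoglycolate phosphatases, so the list tested glycerolipid enzymes only in part. DGD1 (Cre13.g583600), which makes digalactosyl lipid, had 46.5 RPKM at 0 h and 53.3 at 48 h.

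Some genes of fatty acid synthesis were lower late. BCC2 (Cre01.g037850), a biotin carrier of plastid acetyl-CoA carboxylase, and DLA2 (Cre03.g158900), of plastid pyruvate dehydrogenase, changed by -1.58 and -1.49 at 12 h (limma-trend adjusted p = 5.0e-08 and 9.1e-09). Of 15 tested genes, 6 were lower at 12 h and 9 not called, 2 were lower at 24 h, and 4 were lower at 48 h (7 after centring), equally adjusted over the list alone. Some lipase genes rose at the end. LIPG2 (Cre12.g498750), a triacylglycerol lipase, rose from 0.723 to 27.7 RPKM (log2 change 4.05, SE 0.10, limma-trend adjusted p = 4.2e-12) and the lipase-like gene CGLD15 (Cre03.g193500) by 3.13 at 48 h. Of 4 tested genes described as lipases, also grouped after the values were seen, 2 were higher at 48 h and 2 not called. Both tested members of the lipid breakdown list were higher at 48 h (1 after centring), also adjusted over the list alone, among them ECH1 (Cre03.g190850), enoyl-CoA hydratase (1.61). CGLD24 (Cre03.g205050), described as a diacylglycerol acyltransferase, rose by 1.71 at 1 h; with the lysophosphatidate and glycerophosphate acyltransferases it made a group of 3, likewise formed after the values were seen, of which 2 were higher at 1 h (1 after centring). The triacylglycerol synthesis list had 1 tested gene, PAP2, which the table describes as a poly(A) polymerase and which limma-trend called at no time, nor adjusted over the list alone, though at an unadjusted p below 0.05 it was higher at 0.5, 1, 2, 4, 24 and 48 h and lower at 12 h. That list says nothing of oil synthesis.

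Many transcripts for motility were lower from the first sampling. RIB72 (Cre02.g091700), a flagellar microtubule protein, changed by -1.28 at 0.5 h and -3.10 at 48 h, and TUB2 (Cre12.g549550), beta tubulin, by -4.95, with a fitted change along time of -3.93 (SE 0.60, limma-trend adjusted p = 0.00709). The radial spoke gene RSP17 (Cre07.g340400) had a trend of -2.58. Of 56 tested genes, 22 were lower at 0.5 h (32 after centring), 46 at 12 h and 47 at 48 h, equally adjusted over the list alone, and the median was -0.92 and -2.08 at 0.5 and 48 h. Along time 22 fell, 38 adjusted over the list alone. Many chaperone genes fell later: HSP22F (Cre14.g617400), a small heat shock protein, had a trend of -4.09, and CPN60C (Cre06.g309100), a chaperonin, fell by 4.50 at 48 h. Of 30 chaperone genes, 3 were higher and 4 lower at 0.5 h (2 and 4 after centring), 17 were lower at 12 h, and 1 was higher and 19 lower at 48 h, also adjusted over the list alone.

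Genes of protein synthesis were tested in separate lists for the cytosol and the plastid, and not against each other. Cytosolic ribosomal protein genes made no change past 2-fold: at 48 h limma-trend called none of 68 at 2-fold, also adjusted over the list alone, while 55 were higher and 1 lower at an unadjusted p below 0.05 without a limit on size, and the median was 0.29. RPL3 (Cre10.g417700), of the large subunit, had 5304 RPKM at 0 h and 8141 at 48 h. The share of the list in all RPKM was 34.6 and 35.2% at 0 h in duplicates 1 and 2. It was lower at 12 h, with 28.8 and 28.5%, and higher at 48 h, with 43.9 and 42.9%. At 12 h limma-trend had 41 of the 68 lower and 0 higher at an unadjusted p below 0.05. These unadjusted counts were not centred. After centring, the median of the list was -0.06 in place of -0.23 at 12 h and 0.12 in place of 0.29 at 48 h. A share of all RPKM also depends on the level of other genes, which was not separated here. Plastid ribosomal protein genes dipped: 32 of 34 were lower at 12 h and 3 at 48 h, equally adjusted over the list alone, with a median of -2.37 at 12 h and -0.18 at 24 h. After centring, 13 were lower at 48 h. PRPS6 (Cre12.g520600), of the small subunit, went from 417 RPKM at 0 h to 47.1 at 12 h and back to 308 at 24 h (log2 change -3.11 at 12 h, SE 0.09, limma-trend adjusted p = 1.1e-10), and PRPL7/L12 (Cre13.g581650) changed by -2.92. In the proteasome list 8 of 26 were lower at 48 h (14 after centring) and 18 not called, the same adjusted over the list alone, with POA5 (Cre17.g724350), a core subunit, at -1.80. Early on the list leaned up, with medians of 0.63 at 0.5 h and 0.68 at 1 h (0.50 and 0.51 after centring). At both times limma-trend called 0 at 2-fold, while 26 were higher at an unadjusted p below 0.05.

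Cell division genes had several phases. Among 35 tested, 20 were higher at 2 h, 15 higher and 1 lower at 24 h (7 and 1 after centring), and 5 higher and 8 lower at 48 h (3 and 10 after centring), equally adjusted over the list alone. CDKB1 (Cre08.g372550), the mitotic kinase of green plants, rose by 2.14 at 2 h and fell by 1.87 at 48 h, and CYCB1 (Cre08.g370400), a mitotic cyclin, had 18.7 RPKM at 12 h (-1.81), 113 at 24 h and 10.7 at 48 h (-2.61, SE 0.16, limma-trend adjusted p = 7.4e-09). None of the 12 histone genes in the table passed the level filter. The sulfate transporter genes SULTR2 (Cre17.g723350) and SLT1 (Cre12.g502600) changed by -3.02 and -3.50 at 12 h. In the 20-gene list of nitrogen, sulfur and phosphorus supply, 1 was higher and 7 lower at 12 h (1 and 5 after centring), and 9 were lower at 48 h and 11 not called, as when adjusted over the list alone. Of 6 tested genes of autophagy, which recycles cell contents, 1 was higher at 0.5 h (0 after centring), 1 was higher at 2 h, 1 was lower at 12 h and 3 were higher at 48 h (2 after centring), equally adjusted over the list alone, at 48 h among them APG8 (Cre16.g689650), which coats the forming vesicle (1.70), and the conjugation enzyme gene APG3 (1.72). The list's median was 0.72, -0.54 and 1.02 at 0.5, 12 and 48 h, and camera called it at no time (adjusted p = 0.0753 at 48 h).

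The strongest single changes included genes outside these lists. PTA3 (Cre16.g686750), a phosphate transporter gene, rose by 2.52 at 0.5 h and 4.18 at 4 h. Its fitted change along all times was negative, and 4.40 when 24 and 48 h were left out. MOT38 (Cre13.g596700), conserved with motile organisms, went from 4.15 to 46.2 RPKM by 0.5 h (3.11, SE 0.28, limma-trend adjusted p = 3.5e-06) and was back at 2.26 by 12 h. At 48 h AAH1 (Cre01.g029250), an aromatic amino acid hydroxylase, and ETFA (Cre16.g687950), an electron transfer flavoprotein that takes electrons from fatty acid and amino acid breakdown, rose to 244 and 104 RPKM, from 8.25 and 4.01 at 0 h. ELG34 (Cre02.g144050), an exostosin-like glycosyltransferase gene, rose by 3.74. Genes without a symbol were among the largest: Cre03.g163950 rose by 7.03 at 48 h and Cre14.g629600 by 5.33 at 12 h, while the neighbours in name Cre05.g248400 and Cre05.g248450 changed by -6.43 and -6.76 at 48 h.

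The lists were also set against all other genes. Camera with a preset correlation of 0.01 gave 2 lists rising, iron uptake (adjusted p = 4.5e-04) and acetate use (0.00963), and 12 falling out of 25. These were flagella (adjusted p = 1.8e-15), inorganic carbon concentration (1.8e-08), proteasome (1.3e-06), photosystem I (3.6e-06), chaperones (3.6e-06), plastid ribosome (1.3e-05), electron carriers (2.9e-04), photoprotection (3.4e-04), tetrapyrroles (3.4e-04), fatty acid synthesis (0.00408), photosystem II (0.0183) and respiration (0.0494). No call holds with an estimated correlation: in that order, starting with iron uptake and acetate use, camera gave adjusted p = 0.288, 0.606, 0.583, 0.163, 0.606, 0.606, 0.288, 0.680, 0.583, 0.139, 0.606, 0.583, 0.792 and 0.792 with an estimated correlation, and 4 of the 25 lists had an unadjusted p below 0.05. Without the 48 h values 6 lists were called falling, and photosystem I (adjusted p = 0.234), electron carriers (0.229), tetrapyrroles (0.139), fatty acid synthesis (0.139), photosystem II (0.331) and respiration (0.209) were not. Photosystem II also lost its call without 24 h (0.360), and respiration without 0, 2, 4 or 24 h (0.0622, 0.0521, 0.0588 and 0.118). Between 2 and 4 lists rose as single times were left out. At each time against 0 h camera passed 104 of 200 tests and 0 with an estimated correlation, where 30 had an unadjusted p below 0.05. For photosystem I at 48 h the adjusted p was 1.5e-14 and adjusted p = 0.170 with an estimated correlation, and for the plastid ribosome at 12 h 9.4e-14 and adjusted p = 0.351 with an estimated correlation. Among 10000 random lists of like expression, the medians of 2 lists at 48 h lay above the 97.5th percentile and those of 9 below the 2.5th, as a description of these libraries. These were not the same lists as camera called. The 2 were iron uptake and cytosolic ribosome, with acetate use at 96.4. Plastid ribosome (37.1), respiration (38.6), fatty acid synthesis (15.5) and proteasome (4.98), which camera called falling, were not among the 9. Nutrient supply (0.62), which camera did not call, was.

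**Figure D5:**
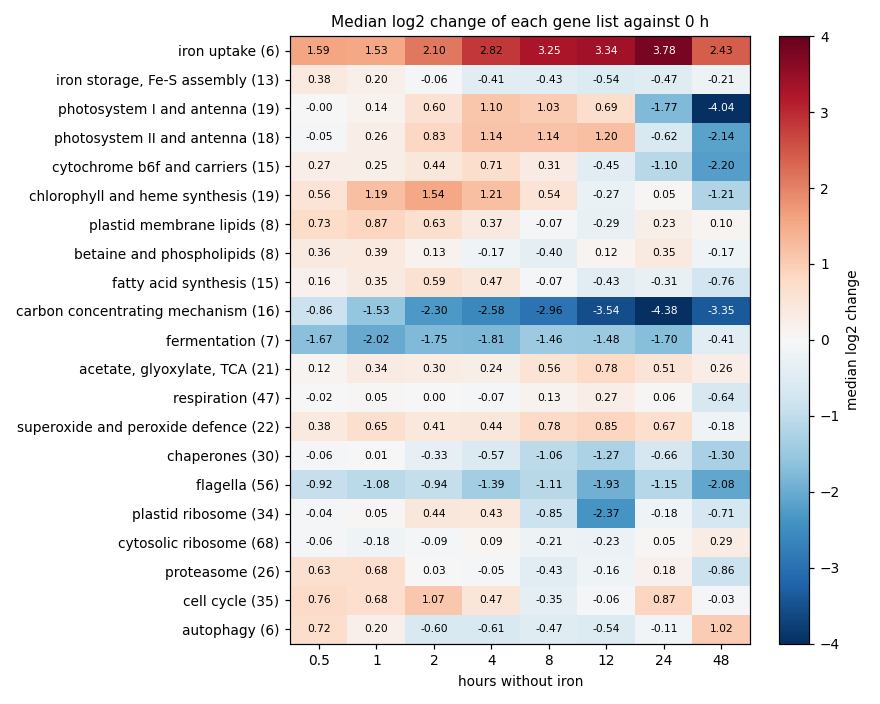
Median log2 change against 0 h of each gene list at each time, with the number of tested genes in parentheses. The values are not centred, and centring changed the sign of several of the small medians. At 24 h, for example, the median of the tetrapyrrole list became -0.28 in place of 0.05. Respiration became -0.26 in place of 0.06 and the proteasome -0.15 in place of 0.18. The photosystem I list went from 1.03 at 8 h to -4.04 at 48 h.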

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

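The tests of each time with both columns and all their alternatives, the fits of each duplicate alone and the trend without 24 and 48 h were chosen only after the data were seen; the others were planned. Not run were edgeR and DESeq2 with RLE or library-size factors and voom, which need counts. The values as deposited are normalized, and the reads recovered for 96.5% of transcripts were not used for tests. Of the trend of named genes, 2729 results kept their side of the threshold, 101 gained and 162 lost it and 20 reversed. Of named genes at a time, 30074 kept their side, 170 gained and 228 lost it and 0 reversed. A reversal was counted only where a fit passed the threshold, so changes of sign without a call are among those kept. Of 49 named genes with a trend, 11 kept an adjusted p below 0.05 in every alternative limma-trend fit that tested them. The threshold of 0.01 was not applied to single genes. The trend, 657 up and 481 down, gave 51 and 37 at an adjusted p below 0.01, 1803 and 779 with hours as such, 798 and 829 with median centring and 316 up with a filter of 5 RPKM. Without 24 and 48 h 1935 fell, and the trend reversed in LHCBM1 (3.28), LHCBM2 (4.68), LHCBM3 (4.14), LHCBM4 (4.51), LHCBM5 (3.48), LHCBM6 (3.47), LHCBM8 (2.58), LHCBM9 (1.498), LHCA1 (1.77), LHCA2 (2.25), LHCA4 (2.70), LHCA5 (2.38), LHCA6 (2.63), LHCA8 (1.53), LHCB5 (1.83), PSAE (1.18), PTA3 (4.40), ECH1 (-2.48), APG8 (-2.05) and LIPG1 (-1.15); that fit leaves out the times at which these genes turn. Leaving out 1 time gave 343 to 592 up and 214 to 898 down. The spline, 6415, gave 3892 with a filter of 5 RPKM, which tests fewer genes, and 4261 to 9532 without 1 time. The 4-fold counts became 123 up and 300 down at 24 h with median centring. With a pseudocount of 0.5 they were 34 up at 0.5 h and 327 up at 24 h. With 5, which shrinks the change of weak genes, they were 26 down at 0.5 h, 97 and 271 at 12 h, 74 and 111 at 24 h and 218 and 373 at 48 h. Against the mean of 0, 0.5 and 1 h, which holds part of the change, 0 and 0 passed at 0.5 h, 137 and 405 at 12 h and 114 and 94 at 24 h. The tested counts became 459 up at 0.5 h and 913 up and 1427 down at 24 h with centring. With a pseudocount of 0.1 they were 1661 up at 0.5 h, 2022 at 12 h and 3145 at 24 h. With 5 they were 172 and 229 at 0.5 h, 541 and 1328 at 12 h, 551 and 539 at 24 h and 1076 and 1282 at 48 h. With a filter of 5 RPKM 869 were up at 12 h, 1117 at 24 h and 1338 at 48 h. Without 1 column, where the lone column left at its time is assumed to vary like the others, they were 736 to 861 up and 452 to 506 down at 0.5 h, 1286 to 1431 and 2313 to 2465 at 12 h, 1879 to 2101 and 773 to 962 at 24 h and 2322 to 2538 and 1863 to 2247 at 48 h. Without a block for the pairing they were 712 and 444, 1312 and 2336, 1920 and 821, and 2394 and 2055 at those times, and of named genes CCP1 and IRT1 at 0.5 h and APG10 and SULTR2 at 2 h lost their call (adjusted p = 0.0711, 0.0591, 0.0875 and 0.0726) and no other changed. Camera, with 2 lists up and 12 down along time, gave 0 and 0 with an estimated correlation, 1 up with hours as such, and 2 to 4 up and 6 to 13 down without 1 time; without 48 h the direction of photosystem II (adjusted p = 0.331) and respiration (0.209) reversed, and over all times left out their adjusted p was 5.1e-04 to 0.360 and 0.00195 to 0.209. The 104 tests passed at single times were 0 with an estimated correlation. Of list medians at 48 h, 16 stayed within the spread between duplicates and 36 moved beyond it. The settings were median centring, which shifts every list by the same amount, and the mean of 24 and 48 h against that of 0 and 0.5 h, another contrast. For centring the outcome thus rests on the spread of 2 duplicates alone. Of further list results along time, 285 kept their side of the threshold, 10 gained and 28 lost it. Except where a setting's construction is named, the cause was not tested. Depth limits genes such as FER2, which had 2 and 4 reads at 0 h, so the size of their rise is poorly set.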

Other observations

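Only the redrawn time orders were planned; the tests of the LHCBM, inorganic carbon and ferritin patterns were chosen only after their results were seen. The times were put in 100 orders, the deposited one included. The linear trend called 1138 genes in the deposited order and at most 1 in any other. The spline called 6415 and at most 78. The counts thus depended on the order of the times. Any drift along time, such as age of the culture, would give the same outcome, and single genes were not tested in this way.

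The fall of the LHCBM genes between 12 and 48 h may be a response of the cells rather than of the counting. Reads shared between near-identical copies would leave the family's sum in place, but the sum changed by -5.53 on the log2 scale (-5.30 and -5.82 in duplicates 1 and 2). A few abundant genes taking most of the reads would move all genes alike, but the family's median changed by -6.12 relative to the median of all genes (-5.97 and -6.04). Growth of the culture and lack of iron cannot be told apart for this pattern, because there were 0 samples of cells grown with iron.

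The early fall of the inorganic carbon genes has an open side as well. Relative to the median of all genes the list changed by -1.98 from 0 to 1 h (-1.73 and -2.26 in duplicates 1 and 2), which the authors' normalization alone could not give. From 0 to 1 h, transfer to fresh medium and lack of iron cannot be told apart, again because there were 0 samples of cells grown with iron. Between 1 and 48 h the list changed by a further -1.87 (-1.88 and -1.97), which a change over by 1 h would not give. How long an effect of the transfer lasts was not measured. For this part too, transfer, age of the culture and lack of iron cannot be told apart.

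FER1 and FER2 rose in the same cells that raised their iron uptake genes. Reads of FER1 counted as FER2 would keep their ratio constant, but the log2 ratio of FER2 to FER1 changed by 3.27 between 12 and 48 h (3.14 and 3.41 in duplicates 1 and 2), as FER2 went from 0.773 and 0.945% of FER1 to 6.80 and 10.1%. Scaling would act on all genes, but at 24 h the smaller of the changes of FER1 and FER2 was 2.099 relative to the median of all genes (1.79 and 2.51). No biological explanation was tested for this pattern.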
